A study of Homo sapiens with 66 samples.

How the data were processed

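RNA from 9 human cell types was compared on 66 arrays with 2 channels each. Per the labels, channel 1 held the cell type and channel 2 held RNA of human umbilical vein endothelial cells (HUVEC), so every array carries the same kind of reference. The groups were HUVEC (n = 10 arrays, HUVEC in both channels), lung microvascular endothelial cells (HMVEC, n = 8), aortic endothelial cells (HAEC, n = 6), coronary artery endothelial cells (HCAEC, n = 6), mammary epithelial cells (HMEC, n = 8), aortic smooth muscle cells (HASMC, n = 8), astrocytes (NHA, n = 8), the hepatocellular carcinoma line HepG2 (n = 6) and epidermal keratinocytes (NHEK, n = 6). Replicates were numbered within each group in the order of deposit. The labels name no donor, culture or extraction, so p-values measure only the spread between arrays, possibly technical. No paired analysis was possible because no label links an array of one group to an array of another.

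The values deposited by the authors are log10 ratios of the 2 channels, with no base, scaling or direction stated. The base was inferred from the values, which have 4 decimals and stop at exactly 2 and -2, and every fold given here assumes base 10. Background correction, normalization, centring and dye assignment before deposit are not given in the sources used here. The deposited log10 ratios were multiplied by 3.3219 to give log2 ratios, with no further scaling. A single cell of 82368 lay outside the limits, in HASMC replicate 1, and was set to missing. Exact zeros made up 0.828% of cells, and 0.308% lay at the limits, where a ratio is a bound. Means and differences of probes with spots at a limit are bounds too, which their SE does not cover, as for PECAM1, VWF, ECSCR, SHE, ADGRL4 and ESM1 in HMEC, PECAM1 and VWF in NHA, CAV1, EFEMP1, ESM1, TMSB4X and AKR1C3 in HepG2, and POSTN in HCAEC. Array medians ran from -1.12 to 0.26 on the log2 scale, and the SD of log2 ratios on an array ran from 0.43 to 2.37. The mean of the array medians ± SD was -0.11 ± 0.21 in HUVEC, 0.04 ± 0.13 in HMVEC, -0.26 ± 0.22 in HAEC and -0.45 ± 0.35 in HCAEC. It was -0.24 ± 0.42 in HMEC, -0.08 ± 0.15 in HASMC, -0.03 ± 0.18 in NHA, -0.15 ± 0.31 in HepG2 and -0.24 ± 0.33 in NHEK.

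The table has 1248 rows. The annotation showed 384 rows printed in 1 spot and 288 probes printed in 3 spots each, a layout inferred from repeated annotation. Spots of a probe had a median correlation across arrays of 0.656, against 0.0437 for random triples of spots. Spots were averaged, which left 672 probes. Of these, 511 had 1 gene symbol (448 genes), 22 had several symbols and were not named, and 139 were unnamed. All 511 matched the RefSeq gene table by gene identifier and 0 symbols changed. Counts are of probes. In the gene lists, a gene with several probes was represented by the probe with the fewest missing values, then by order in the table, and probes of a gene that were called in opposite directions are named as such.

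The direction of the ratios is not given in the labels and was taken as cell type over HUVEC reference. Before the data were examined, a direction was to be called likely only if it was borne out by pan-endothelial markers in the non-endothelial groups and by hepatocyte markers in HepG2. The pan-endothelial markers were low in the non-endothelial groups. The hepatocyte list had a single measured gene, ITIH4, which did not pass the test, so the direction rests on the first check alone. If the direction were the opposite, every count would stay and higher and lower would be exchanged.

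Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) in a fit of 1 mean per group over all 66 arrays, with 57 residual degrees of freedom, so that all comparisons share an estimate of the spread. Where a side holds several cell types, their group means were weighted equally. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the 672 probes of a comparison. A probe was endothelial-restricted when each of the 4 endothelial groups was above each of the 5 others, in all 20 pairwise contrasts. The tests, the gene lists and the rule for named genes were chosen before the data were examined. By that rule the text draws on the 12 highest and 12 lowest differences among called probes with 1 symbol for endothelial against non-endothelial cells, the 10 and 10 for HMVEC and for arterial cells, the 8 and 4 for each non-endothelial type, and the 5 and 5 for HCAEC against HAEC and NHEK against HMEC, plus up to 4 members of a list with the largest absolute t and members that go against their list. XIST and Y-linked genes were left out, and a gene was taken once, by its largest difference.

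There were 16 gene lists. Lists with at least 3 measured genes were tested with camera in limma, first with a correlation between genes preset at 0.01 and then with an estimated correlation, adjusted over the lists of a comparison. They were pan-endothelial markers (25 measured), lymphatic and microvascular markers (11), fibroblast and mesenchymal matrix genes (8), haemostasis and fibrinolysis genes (6), vascular growth factor, Tie, Eph and Notch signalling (6), ribosomal, translation and housekeeping genes (6), arterial markers (5), venous markers (3), leukocyte adhesion and cytokine genes (3), and interferon and antigen presentation genes (3). Smooth muscle, epithelial and hepatocyte lists had 1 measured gene each, ACTN1, ITGA6 and ITIH4. Astrocyte, proliferation and blood cell lists had 0 measured genes.

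Arrays within HMVEC, HMEC, HASMC, NHA, HepG2 and NHEK fell into equal sets by the sign of their correlation with the mean HUVEC array (4 and 4, or 3 and 3), while all HUVEC, HAEC and HCAEC arrays had a positive sign. This sign is called dye orientation below. It was read from the data and is not given in the labels, and the name is a shorthand since whether dye underlies it was not settled. Values with it as a covariate were added after seeing the data. In fits where the signs of arrays were turned, it was kept as read before turning. Turning reverses the correlation it was read from, so the covariate may be wrong for those arrays. HAEC replicates 1 and 2 correlated at r = -0.482 across probes, and HCAEC replicates 1 and 2 at r = -0.660, below a limit of -0.3 fixed at the outset, so the direction of these 4 arrays is not settled. With the difference of the later arrays of their group from HUVEC replicates 9 and 10, replicate 1 correlated at 0.370 in HAEC and 0.386 in HCAEC, and replicate 2 at -0.519 and -0.310. Replicate 2 is thus the one that runs against the later arrays. The plan was to give sizes without direction for such arrays. In a departure from it, comparisons of HAEC and HCAEC are given with directions as deposited, beside values without these arrays with the signs of replicate 2 turned, and with the signs of replicate 1 turned.

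Alternatives chosen at the outset were median centring of each array, quantile normalization, 2 missing-value filters, averaging of arrays with consecutive serial numbers, a fit on the compared groups alone, subsets of the HUVEC arrays, robust empirical Bayes and leaving out each array. Every one of the 672 probes had enough values to be tested, and neither filter removed a probe, so the filters test nothing. Centring moved the median difference over all probes from 0.42 to 0.03 for HMVEC against large-vessel cells, from -0.18 to 0.10 for arterial cells against HUVEC and from -0.06 to 0.11 for HCAEC against HAEC. It moved it from 0.18 to 0.06 for HASMC, from 0.27 to 0.09 for NHA, from -0.21 to 0.06 for HepG2 and from -0.21 to 0.08 for NHEK, each against endothelial cells, and from -0.14 to 0.12 for NHEK against HMEC. The procedure was tested on simulated data with 200 of 672 probes changed. The simulated noise was independent between arrays, with no orientation effect, no like or opposed arrays and no values at the limits. The shares recovered may thus not hold for the real arrays. For endothelial against non-endothelial cells it recovered 46.3% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 100% of changes of 2. For arterial cells against HUVEC the shares were 14.9%, 62.7% and 97.0%, and for HCAEC against HAEC 4.5%, 38.8% and 86.4%. Intervals of correlations are 95% bootstrap intervals from 2000 draws of probes or genes, computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9. Signal over background is not in the deposited ratios.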

Results

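The data are expression ratios for 672 probes in 9 cultured human cell types, each hybridised against HUVEC RNA. Under the series title, which names endothelial cell profiles, the arrays place 4 endothelial types (HUVEC, HMVEC, HAEC and HCAEC, 30 arrays) beside 5 non-endothelial types (HMEC, HASMC, NHA, HepG2 and NHEK, 36 arrays). The comparisons ask which transcripts set endothelial cells apart from other cells, and how endothelial cells of different vessels differ. Differences are on the log2 scale ± SE.

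PECAM1 (chromosome 17), an adhesion molecule of endothelial junctions, was 27.2-fold higher in endothelial than in non-endothelial cells (log2 difference 4.77 ± 0.39, n = 30 and 36 arrays, adjusted p = 7.9e-17). CD93 (chromosome 20), a lectin-like endothelial receptor, was 24.5-fold higher (4.62 ± 0.30), ECSCR (chromosome 5), an endothelial surface protein, 19.9-fold (4.32 ± 0.22), and CDH5 (chromosome 16), the cadherin of endothelial junctions, 16.8-fold (4.07 ± 0.26). For CD93, ECSCR and CDH5, all 30 endothelial arrays lay above the non-endothelial mean and all 36 non-endothelial arrays lay below the endothelial mean. For PECAM1 these were 30 of 30 and 34 of 36. Single arrays still overlapped for CD93, at -0.48 in HMEC replicate 7 and -1.85 in HCAEC replicate 3. They overlapped for CDH5 as well, at -0.83 in NHEK replicate 1 and -1.47 in HCAEC replicate 5. The other genes with the highest differences were SHE (4.19), EFEMP1, a fibulin of the matrix (4.18), ESM1, which encodes endocan (4.01), CLEC14A (3.97), ROBO4, a guidance receptor of vessels (3.68), ADGRL4 (3.56), MCAM (3.37) and S1PR1, a receptor for sphingosine 1-phosphate (3.36). Lower in endothelial cells were FN1, which encodes fibronectin (-2.71 ± 0.33), ITGA6, an integrin of epithelial basement membrane contacts (-2.25 ± 0.22), and the glycolytic enzyme genes TPI1 (-2.14 ± 0.21) and LDHA (-1.63 ± 0.20). NPC1, which moves cholesterol out of lysosomes, was at -1.77 ± 0.10, TUBA1A at -1.90, DDOST at -1.97, CCT7 at -1.80 and SF3A3 at -1.74. The pseudogene USP32P2 was at -2.10. DDX3X (-1.64) had another probe at 0.38, called in the opposite direction, and RCC2 was at -1.58.

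Among 672 probes, limma called 193 higher and 183 lower in endothelial cells, of which 105 and 65 differed by at least 1 on the log2 scale. With dye orientation as a covariate 238 were higher and 149 lower, and 311 probes were called in both fits. Without HAEC and HCAEC replicates 1 and 2 the balance turned, with 160 higher and 222 lower, 338 of them shared. Without HepG2 and NHEK 147 were higher and 160 lower, and USP32P2 (-0.45, adjusted p = 0.075), DDX3X (-0.16, adjusted p = 0.49) and RCC2 (-0.36, adjusted p = 0.061) were no longer called. On the arrays with serial numbers 1 to 40, which hold HUVEC, HMVEC, HMEC, HASMC and NHA, 154 were higher and 53 lower, and ITGA6, DDOST, TUBA1A, CCT7 and SF3A3 were not called either.

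Of 25 pan-endothelial markers measured, 21 were higher in endothelial cells, 1 was lower and 3 did not pass the test, and the counts were 21 and 1 adjusted over the list alone. Their median difference was 2.68, and camera placed the list above other genes (adjusted p = 1.0e-11), a call that did not hold with an estimated correlation (adjusted p = 0.12 with an estimated correlation). The list also serves as the basis for the direction of the ratios, so its sign is not independent evidence. VWF, the carrier of coagulation factor VIII (3.27), EDN1, the endothelin gene (2.71), and ANGPT2, a ligand of the Tie receptor (2.88), were among the members called. ENG (0.17), RAMP2 (0.00) and THBD (0.44) did not pass, though with dye orientation as a covariate ENG (1.01, adjusted p = 0.00054) and THBD (0.68, adjusted p = 0.047) did. TFPI, an inhibitor of coagulation, was the lower member (-0.38), and its other probe was called in the opposite direction (2.13). Vascular growth factor and Tie signalling genes were higher for 5 of 6 (5 adjusted over the list alone; median 1.59; adjusted p = 0.032), led by ANGPT2, EDN1 and the receptor KDR (2.33 ± 0.28), with adjusted p = 0.30 with an estimated correlation.

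Ribosomal, translation and housekeeping genes lay lower in endothelial cells for 4 of 6, with 1 higher, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.30 with an estimated correlation). With arrays centred on their medians the direction stayed and the call was lost (adjusted p = 0.055). RPL4 (-1.36), GAPDH (-1.27) and TUBA1A (-1.90) were lower and RPL19 was higher (0.46). Against endothelial cells RPL4 was at 2.64 in HepG2 and 2.85 in NHEK, while it was not called in HMEC (0.52), HASMC (0.45) or NHA (0.34). Not every member had this pattern, since EEF1A1 was called higher in HASMC (0.48) and RPL19 lower in NHA (-0.66). Of the differences between these types, only that of NHEK against HMEC was tested for the list, and it is given below. TUBA1A, called in NHA (1.65), was not called in HMEC (0.01) or HASMC (0.27). Of 11 lymphatic and microvascular markers 6 were higher and 2 lower, both over all genes and adjusted over the list alone, among them the matrix laminin LAMA4 (2.64) and the fatty acid binding protein genes FABP5 (1.84) and FABP4 (1.81). Arterial markers were higher for 4 of 5, venous markers for 2 of 3 with 1 lower, matrix genes for 4 of 8 with 1 lower, haemostasis genes for 3 of 6 with 1 lower, leukocyte adhesion genes for 2 of 3 with 1 lower, and interferon genes for 1 of 3. These counts were the same adjusted over the list alone. None of these 7 lists passed camera over other genes, with adjusted p from 0.21 to 0.72. The 3 interferon genes had a median of -0.35 and a mean of 0.05, and the direction of their test turned under centring. ITGA6 was the measured gene of the epithelial list. ACTN1 (0.13) of the smooth muscle list and ITIH4 (-0.37) of the hepatocyte list did not pass.

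Endothelial-restricted probes, higher in each of the 4 endothelial groups than in each of the 5 other groups, numbered 25 for 24 genes, and 0 probes were lower in all 20 contrasts by limma. With dye orientation as a covariate 34 passed, the 25 among them. The gap between the lowest endothelial mean and the highest other mean was widest for PECAM1 (3.36), ECSCR (2.64), CDH5, VWF (2.47), S1PR1 (2.38), CLEC14A (2.37), SHE (2.35) and ROBO4 (2.31). CD93, MYCT1, ESM1, FGD5, MCAM, PPP1R16B, PRKACA, PLSCR4, BMP6, JCAD, HHIP, EMCN, PALMD, NTN4, THBS1 and SEC14L1 followed, with gaps from 2.14 to 0.85. Of the 3 probes of VWF 1 was restricted, as was 1 of the 3 of THBS1, 1 of the 2 of EMCN, 1 of the 2 of PPP1R16B and 2 of the 3 of PECAM1. Probes of THBS1 were called in opposite directions in NHEK against endothelial cells (-1.45 and 1.15), and the other EMCN probe was not called in HMEC (adjusted p = 0.75), HASMC (adjusted p = 0.23) or NHA (adjusted p = 0.14). Without HAEC and HCAEC replicates 1 and 2, 15 probes passed.

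**Figure D1:**
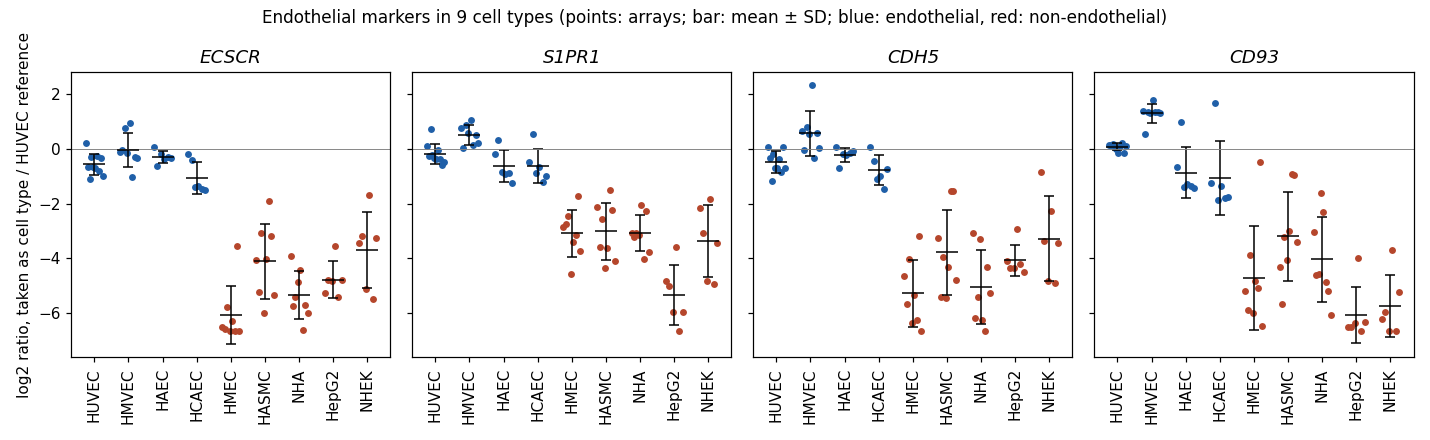
Log2 ratios, taken as cell type over HUVEC reference (vertical axis), of ECSCR, S1PR1, CDH5 and CD93 in the 9 cell types (horizontal axis), with endothelial types in blue and non-endothelial types in red. Points are arrays and bars are the group mean ± SD, and the ECSCR mean was -0.55 in HUVEC and -6.09 in HMEC, where 3 of 8 arrays lay at the lower limit of the scale.

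Mammary epithelial cells (HMEC, 8 arrays) had 13.5-fold more of the integrin ITGA6 than endothelial cells (30 arrays; 3.76 ± 0.34, adjusted p = 1.6e-14), in 8 of 8 arrays. NPC1 (2.27 ± 0.16), the cholesterol synthesis gene MSMO1 (2.06 ± 0.40), LDHA (1.99 ± 0.32) and TANC2 (2.42 ± 0.38) were also higher, as were SUGT1P3 (1.65), LOC100129931 (1.54) and the proteasome activator gene PSME4 (1.27). Among the lowest were ADGRL4 (-5.63), ECSCR (-5.60), PECAM1 (-5.35) and SHE (-5.25). Their order cannot be read, since 3 of 8 arrays for ADGRL4, ECSCR and SHE and 4 of 8 for PECAM1 lay at the lower limit of the scale. Matrix genes lay lower for 6 of 8, also 6 adjusted over the list alone (median -2.26, camera adjusted p = 4.1e-04, adjusted p = 0.048 with an estimated correlation), led by CCN2 (-4.48), POSTN (-3.09), LOX (-2.59) and SPARC (-2.52). Vascular growth factor genes were lower for 3 of 6, and 3 adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.28 with an estimated correlation). Limma called 70 probes higher and 155 lower, 75 and 184 with dye orientation as a covariate, 141 and 138 after quantile normalization, and 127 and 144 without HAEC and HCAEC replicates 1 and 2.

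Aortic smooth muscle cells (HASMC, 8 arrays) had 13.7-fold more CXCL12, a chemokine, than endothelial cells (3.78 ± 0.53, adjusted p = 4.6e-08), in 8 of 8 arrays, and 8.43-fold more LOX, an enzyme that crosslinks collagen (3.08 ± 0.27). OGN (2.43 ± 0.58), the heat shock gene HSPH1 (2.23), the matrix protease gene MMP2 (2.15), FN1 (2.11), C1orf198 (2.09) and POSTN, which encodes periostin (2.08), were higher as well. Another FN1 probe, which stands for the gene in the matrix list, was at 1.37 and not called by limma (adjusted p = 0.077). The POSTN size is a bound, since 2 of 8 arrays had a spot at the upper limit of the scale. PECAM1 (-4.44), ECSCR (-3.62), CDH5 (-3.56) and ROBO4 (-3.36) were lowest. Matrix genes were higher for 4 of 8 with 0 lower, and for 5 with 1 lower adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.16 with an estimated correlation). Limma called 83 probes higher and 95 lower, 72 and 127 with dye orientation as a covariate, 70 and 115 with arrays centred, and 118 and 90 without HAEC and HCAEC replicates 1 and 2, which turns the balance. On arrays of 1 orientation OGN (adjusted p = 0.059), FN1 (adjusted p = 0.065) and POSTN (adjusted p = 0.14) were not called, and FN1 fell to 0.83 (adjusted p = 0.19) with the signs of HAEC and HCAEC replicate 2 turned and dye orientation as a covariate. That covariate was kept as read before turning.

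Astrocytes (NHA, 8 arrays) shared with HASMC the highest genes, CXCL12 (3.93 ± 0.53, 15.2-fold, adjusted p = 8.1e-09, in 8 of 8 arrays) and LOX (2.74 ± 0.27). The cyclin gene CCND1 (2.52), HSPH1 (2.49), KBTBD11 (2.37), the spindle gene TPX2 (2.36 ± 0.64), C1orf198 (2.20) and FN1 (2.10) were higher, and PECAM1 (-5.82), ECSCR (-4.86), CDH5 (-4.84) and the matrix gene ABI3BP (-4.72) lowest. Vascular growth factor genes were lower for 5 of 6, and 5 adjusted over the list alone (adjusted p = 0.0030, and adjusted p = 0.14 with an estimated correlation), among them EDN1 (-2.96) and KDR (-2.90). Pan-endothelial markers were lower for 19 of 25 in NHA and in HMEC, with TFPI higher in each, both over all genes and adjusted over the list alone (adjusted p = 1.7e-14 and 1.7e-10, and adjusted p = 0.053 and 0.091 with an estimated correlation). In HASMC they were lower for 14 with TFPI higher, and for 16 and 1 adjusted over the list alone (adjusted p = 3.0e-11, and adjusted p = 0.14 with an estimated correlation). The other TFPI probe was called lower in NHA (-2.69), HMEC (-4.28) and HASMC (-0.96). Arterial markers were lower for 3 of 5, and 3 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.14 with an estimated correlation), ALDH1A1 (-3.80), DEPP1 (-3.03) and ACVRL1 (-1.57). Limma called 107 probes higher and 119 lower, 97 and 143 with dye orientation as a covariate, 82 and 139 with arrays centred, and 170 and 114 without HAEC and HCAEC replicates 1 and 2, which turns the balance. FN1 stood at 0.82 (adjusted p = 0.16) with the signs of HAEC and HCAEC replicate 2 turned and dye orientation as a covariate, and TPX2 at 1.99 (adjusted p = 0.060) on arrays 1 to 40, neither called. The covariate was kept as read before the signs were turned.

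HepG2 cells (6 arrays) had 38.6-fold more FN1 (5.27 ± 0.66, adjusted p = 2.9e-10) and 31.2-fold more AKR1C3, a steroid-converting reductase (4.97 ± 0.32), than endothelial cells, each in 6 of 6 arrays. USP32P2 (4.82), DDX3X (4.43, other probe -0.54), TPI1 (4.36), the anchoring protein gene AKAP12 (4.29), TGOLN2 of the Golgi (4.27) and the chaperone gene HSPA8 (4.25) were higher. The actin-binding gene TMSB4X (-6.29), CAV1, which forms caveolae (-6.09), CD93 (-5.93) and EFEMP1 (-5.82) were among the lowest. Spots lay at the lower limit of the scale in 3 of 6 arrays for TMSB4X and 5 of 6 for CAV1 and EFEMP1. They lay at the upper limit in 3 of 6 for AKR1C3 and in 2 of 6 for TPI1, so these sizes are bounds. Pan-endothelial markers were lower for 23 of 25, and 23 adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.33 with an estimated correlation). Ribosomal and housekeeping genes were higher for 5 of 6, and 5 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.33 with an estimated correlation), with TUBA1A at 4.19, RPL4 at 2.64 and RPS3 at 1.88. Limma called 177 probes higher and 221 lower, 169 and 295 with dye orientation as a covariate, 220 and 192 with arrays centred, and 192 and 198 without HAEC and HCAEC replicates 1 and 2. In this comparison 7 genes had probes called in opposite directions, VWF (-3.34 and 1.11) and TFPI (-0.49 and 1.18) of the pan-endothelial list among them.

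Keratinocytes (NHEK, 6 arrays) had more USP32P2 (4.31 ± 0.32) and 19.1-fold more ITGA6 (4.25 ± 0.39, adjusted p = 1.1e-14) than endothelial cells, each in 6 of 6 arrays. FN1 (3.85), RCC2 (3.71), DDOST (3.54), TUBA1A (3.40), the ribosomal gene RPL29 (3.32) and DDX3X (3.27, other probe -0.87) were higher, and CD93 (-5.60), EFEMP1 (-5.22), ESM1 (-4.33) and ANGPT2 (-4.28) were among the lowest. Spots of CD93, EFEMP1 and ESM1 lay at the lower limit of the scale in 2 of 6 arrays each, so these sizes are bounds. Pan-endothelial markers were lower for 21 of 25, and 21 adjusted over the list alone (adjusted p = 1.7e-06, and adjusted p = 0.33 with an estimated correlation). Ribosomal genes were higher for 4 of 6 with RPL19 lower (-0.60), and 4 and 1 adjusted over the list alone (adjusted p = 0.0037, and adjusted p = 0.18 with an estimated correlation). Limma called 144 probes higher and 197 lower, 144 and 287 with dye orientation as a covariate, 184 and 161 with arrays centred, and 162 and 186 without HAEC and HCAEC replicates 1 and 2. Across probes, which are not independent replicates, the NHEK mean correlated at 0.819 with HepG2 and at 0.629 with HMEC.

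Between the epithelial types, keratinocytes (6 arrays) had more USP32P2 (4.30 ± 0.39), FN1 (3.71 ± 0.80) and TUBA1A (3.39 ± 0.46, adjusted p = 1.9e-08, in 6 of 6 arrays) than HMEC (8 arrays). VWF was at 3.87, with other probes at 0.31 and 0.53, and PECAM1 at 3.53, with other probes at 2.45 and 1.04 (adjusted p = 0.35 for the last). Both differences are bounds, since the VWF probe lay at the lower limit of the scale in 3 of 8 HMEC arrays and the PECAM1 probe in 2 of 8. Of 25 pan-endothelial markers 5 were higher and 4 lower, both over all genes and adjusted over the list alone (adjusted p = 0.68). DEPP1 (-3.20 ± 0.35), the ribosomal gene RPS15 (-2.86), ITM2A (-2.63), the prostaglandin transporter gene SLCO2A1 (-2.52) and the endothelial mucin gene EMCN (-2.33, not called with exact zeros as missing, adjusted p = 0.059) were lower. Ribosomal and housekeeping genes were higher for 4 of 6, and 4 adjusted over the list alone (adjusted p = 0.0088, and adjusted p = 0.20 with an estimated correlation), and matrix genes for 5 of 8, and 5 adjusted over the list alone (adjusted p = 0.062). Limma called 154 probes higher and 101 lower, 164 and 129 with dye orientation as a covariate, and 81 and 57 after quantile normalization.

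Lung microvascular cells (HMVEC, 8 arrays) were compared with large-vessel cells (HUVEC, HAEC and HCAEC, 22 arrays). HMVEC is the only small-vessel type here and comes from lung, so vessel size and organ cannot be told apart. Its arrays fill serial numbers 9 to 16. They have 4 of each dye orientation, while all large-vessel arrays are positive, so the sides are not balanced for it. In HMVEC, GMFG, a regulator of actin branching, was 11.4-fold higher (3.51 ± 0.32, adjusted p = 3.5e-13) and CD34, a surface sialomucin, 9.33-fold (3.22 ± 0.39), each in 8 of 8 arrays. TM4SF18 (2.87), the growth factor receptor gene KDR (2.83 ± 0.49), ADGRF5 (2.78), the mannose receptor gene MRC1 (2.63), USP18, which removes ISG15 (2.58), ITGA6 (2.35), LDB2 (2.09) and RASSF2 (2.05) were higher. MGP, an inhibitor of calcification, was lower (-3.04 ± 0.52), as were MMP2 (-1.93), PAK2 (-1.84), AKR1C3 (-1.67), OSGIN2 (-1.60), LOX (-1.31), the interferon-induced gene OAS1 (-1.26), FLRT2 (-0.84), UGP2 (-0.69) and ANXA5 (-0.63). The other probes of PAK2 did not pass (0.84, 0.39 and 0.77), and with dye orientation as a covariate UGP2 (adjusted p = 0.13) and ANXA5 (adjusted p = 0.079) were not called. On arrays of 1 orientation these and also LOX (-0.98, adjusted p = 0.069) and OAS1 (-1.17, adjusted p = 0.076) were not called.

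Pan-endothelial markers were higher in HMVEC for 7 of 25 with MGP lower, and for 11 with 1 lower adjusted over the list alone (camera adjusted p = 0.76). Microvascular markers were higher for 3 of 11, and 3 adjusted over the list alone, namely ITGA6, CAV1 (0.80) and FABP5 (0.70), with adjusted p = 0.76 for the list. Matrix genes lay lower by camera (adjusted p = 7.7e-04, and adjusted p = 0.047 with an estimated correlation) on LOX and MMP2, which were the called members both over all genes and adjusted over the list alone, while the list had a mean of -0.42 and a median of 0.04. Limma called 99 probes higher and 15 lower, 60 and 24 with dye orientation as a covariate, 33 and 40 with arrays centred, and 83 and 114 after quantile normalization. Without HAEC and HCAEC replicates 1 and 2 it called 207 and 14.

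Arterial cells (HAEC and HCAEC, 12 arrays) were set against venous HUVEC (10 arrays). HUVEC is the only venous type and comes from the umbilical vein, so artery against vein and site of origin cannot be told apart. The arterial arrays have serial numbers 53 to 66, while HUVEC replicates 1 to 8 have serial numbers 1 to 8. In arterial cells POSTN was 8.53-fold higher (3.09 ± 0.57, adjusted p = 3.6e-04, in 10 of 12 arrays), a bound since 4 of 6 HCAEC arrays had a spot at the upper limit of the scale. The chemokine gene CCL2 (1.79 ± 0.53, in 7 of 12), THBD, the thrombin receptor thrombomodulin (1.66 ± 0.48), ABI3BP (1.17), the arterial marker DEPP1 (1.06 ± 0.27), B2M of antigen presentation (0.91 ± 0.18) and PLK2 (0.51) were higher. For CCL2 the mean was 3.52 in HCAEC, but -0.22 in HAEC and -0.14 in HUVEC, so its difference comes from HCAEC. FAM110D (-2.26 ± 0.56), AKAP12 (-1.43 ± 0.28), GGH (-1.06), METTL14, an RNA methylation gene (-0.99), HNRNPF (-0.93), the proteasome gene PSMD2 (-0.90), RBM25 (-0.77), PLXNA2 (-0.77), TFG (-0.69) and the DNA repair gene PRKDC (-0.68) were lower. With arrays centred the last 8 were not called. Averaging arrays of consecutive serial numbers left POSTN, THBD, B2M and GGH called, and ended the calls of CCL2 (adjusted p = 0.12), ABI3BP and DEPP1 (adjusted p = 0.076 for each), PLK2 (adjusted p = 0.067), FAM110D and AKAP12 (adjusted p = 0.051 for each) and the others. Quantile normalization ended those of CCL2 (adjusted p = 0.058), RBM25 (adjusted p = 0.066) and PRKDC (adjusted p = 0.084). With HUVEC replicates 1 to 8 alone those ended were CCL2 (adjusted p = 0.053), ABI3BP (adjusted p = 0.065), PLK2 (adjusted p = 0.067) and PLXNA2 (adjusted p = 0.059). With HUVEC replicates 9 and 10 alone 0 of the 17 named genes stayed called, though each kept its direction. With exact zeros as missing THBD was not called (adjusted p = 0.058). A fit on HAEC, HCAEC and HUVEC alone left POSTN, ABI3BP, B2M, PLK2 and GGH called and ended the other calls. There CCL2 was at adjusted p = 0.086 and THBD, FAM110D and AKAP12 at adjusted p = 0.054 each. Of 5 arterial markers 1 was higher, DEPP1, and 1 adjusted over the list alone (adjusted p = 0.72), with a median of -0.28 and a mean of -0.23 where the test pointed up. Of 3 venous markers 0 passed over all genes by limma and 1 was lower adjusted over the list alone, VWF (-1.02). No list passed camera, the lowest being leukocyte adhesion genes (adjusted p = 0.080).

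Limma called 8 probes higher and 15 lower in arterial cells, 109 at an unadjusted p under 0.05, with 15 and 3 when arrays were centred and 31 and 29 after quantile normalization. HAEC replicates 1 and 2 correlated negatively, as did HCAEC replicates 1 and 2, and without these 4 arrays 16 were higher and 124 lower, the 23 among them. On arrays 57 to 66 alone 49 were higher and 226 lower. With the signs of replicate 2 turned and dye orientation, kept as read before turning, as a covariate 22 were higher and 84 lower. With the signs of replicate 1 turned in place of replicate 2, 2 were higher and 20 lower. In that fit POSTN (2.22, adjusted p = 0.061), CCL2 (1.34, adjusted p = 0.22), ABI3BP (0.98, adjusted p = 0.11), B2M (0.64, adjusted p = 0.079), PLK2 (0.39, adjusted p = 0.11) and PRKDC (-0.66, adjusted p = 0.063) were not called. Leaving out HAEC replicate 1 gave 41 calls, HAEC replicate 2 gave 48, HCAEC replicate 1 gave 49 and HCAEC replicate 2 gave 56, while leaving out HAEC replicate 5 gave 12 and HAEC replicates 3, 4 or 6 or HCAEC replicates 3, 4, 5 or 6 gave 13. All 17 named genes kept their direction without the 4 arrays and with either replicate turned.

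Coronary cells (HCAEC, 6 arrays) had 13.4-fold more CCL2 than aortic cells (HAEC, 6 arrays; 3.75 ± 0.71, adjusted p = 0.0014, in 5 of 6 arrays). ITM2A (1.81), AKAP12 (1.46), the basement membrane collagen gene COL4A2 (1.38 ± 0.34) and a probe for PAK2 (1.82, others -0.75, 0.03 and 0.09) were higher. The crosslinking enzyme gene TGM2 (-1.90 ± 0.49), AKR1C3 (-1.89 ± 0.42), GIMAP7 (-1.82), ITGA6 (-1.81) and TOM1 (-1.65) were lower. Leukocyte adhesion genes were higher for 1 of 3, CCL2, and for 2 with 1 lower adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.058 with an estimated correlation). Limma called 6 probes higher and 8 lower, 8 and 7 with arrays centred, 20 and 32 after quantile normalization, and 14 and 29 without HAEC and HCAEC replicates 1 and 2. On arrays 57 to 66 alone it called 87 and 205. With the signs of replicate 2 turned it called 10 and 15, and with those of replicate 1 turned 4 and 10. In the latter PAK2 (1.69, adjusted p = 0.093), ITM2A (1.37, adjusted p = 0.38) and GIMAP7 (-1.37, adjusted p = 0.38) were not called. Averaging arrays of consecutive serial numbers ended the calls of ITM2A (adjusted p = 0.087), AKAP12 (adjusted p = 0.13) and GIMAP7 (adjusted p = 0.11). Centring ended that of TOM1 (-1.48, adjusted p = 0.054). Robust empirical Bayes ended those of PAK2 and ITM2A (adjusted p = 0.050 for each). A fit on these 12 arrays alone called 0 by limma, with 106 at an unadjusted p under 0.05. Leaving out HAEC replicate 1 gave 9 calls, HCAEC replicate 1 gave 24, HCAEC replicate 2 gave 26, HAEC replicate 5 gave 3, HAEC replicates 3, 4 or 6 gave 4, and HCAEC replicates 3, 4, 5 or 6 gave 5.

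**Figure D2:**
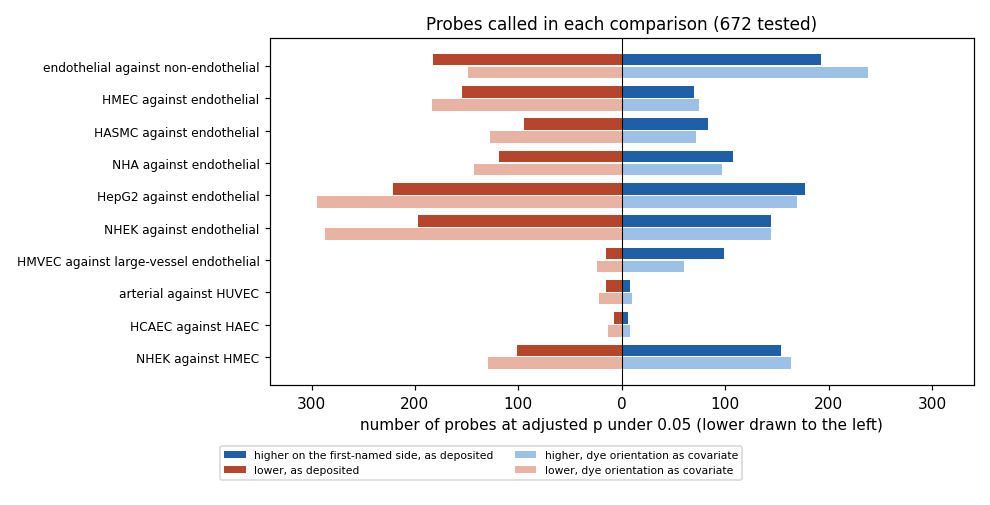
Number of probes called in each of the 10 comparisons, with those higher on the first-named side to the right and those lower to the left (horizontal axis), as deposited in dark bars and with dye orientation as a covariate in light bars. HepG2 had 177 higher and 221 lower and HCAEC against HAEC 6 higher and 8 lower as deposited.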

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

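The tests of dye bias, of unturned signs and of NHEK against HepG2 in this part were chosen only after the results they test were seen, and the comparison of NHEK across opposite dye orientations replaced a test that could not decide, after its own result was seen.

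Among 54 groups of arrays tested for 1 array far from the rest, 10 were found, where chance gives about 1 in 20, or 2.7, and the genes were the endothelial markers ECSCR, S1PR1, CDH5 and CD93. That rate assumes values not cut at a limit. It need not hold for ECSCR in HMEC or CD93 in HepG2, where 3 of 8 and 1 of 6 arrays lay at the lower limit. In HMEC replicate 7, ECSCR was -3.55 against -6.64 to -5.77 in the others, a gap of 0.718 of the range, and CD93 was -0.48 against -6.46 to -3.86, a gap of 0.566. In HepG2 replicate 4, ECSCR was -3.53 (gap 0.656), CDH5 -2.93 (gap 0.733) and CD93 -4.00 (gap 0.883), each above the other arrays. In HMVEC, CDH5 was 2.35 in replicate 5 against at most 0.79 (gap 0.580), and CD93 was 0.56 in replicate 2 against at least 1.32 (gap 0.605). S1PR1 was 0.72 in HUVEC replicate 3 against at most 0.10 (gap 0.48). CD93 was 0.97 in HAEC replicate 2 against at most -0.67 (gap 0.690), and 1.68 in HCAEC replicate 2 against at most -1.24 (gap 0.827). The direction of these 2 arrays is not settled. Over all rows, the SD of log2 ratios was the lowest of its group in HMEC replicate 7 (1.04) and HepG2 replicate 4 (1.78). It was the highest of its group in HMVEC replicate 5 (1.68) and HUVEC replicate 3 (1.55). Whether this accounts for the gaps was not tested.

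Arrays with odd and even serial numbers differed within HMVEC, HMEC, HASMC, NHA, HepG2 and NHEK. Across probes, the difference between even and odd arrays correlated with the mean of the HUVEC arrays, which hold HUVEC in both channels, at an absolute r of at least 0.623 in all 6 groups. These sets are also the arrays of positive and of negative correlation with that mean, so the value restates how they were found and cannot test a gene-specific dye bias, with the sign of swapped arrays turned before deposit, which stays open. No biological explanation was tested, since the labels give none for odd and even arrays.

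HAEC replicates 1 and 2, and HCAEC replicates 1 and 2, ran against each other. The difference between the paired arrays correlated with the difference of the later arrays of the same group from HUVEC replicates 9 and 10, at r = 0.526 (interval 0.442 to 0.605) for HAEC and 0.378 (0.255 to 0.490) for HCAEC, so that a swapped array whose sign was left unturned may account for both. Dye bias on a turned array would give opposite correlations with the HUVEC mean, but in HAEC these were 0.2785 and 0.279 (lowest bound 0.213), which argues against it. In HCAEC they were 0.1415 (0.0572 to 0.224) and 0.238 (0.187 to 0.288), of the same sign but with a lower bound too near 0 to exclude that bias. No biological explanation was tested, as the labels give no difference between replicates.

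The NHEK profile correlated more with HepG2 (0.819) than with HMEC (0.629), a difference of 0.190 (interval 0.129 to 0.255). Each of these group means averages equal numbers of arrays of both orientations. An orientation effect of equal size on the arrays of a group thus cancels from them. Between arrays of opposite dye orientation the difference was 0.1492 (0.0794 to 0.221) and 0.191 (0.130 to 0.262), which argues against shared dye orientation as the whole source. A technical effect shared by the arrays with serial numbers 41 to 52, which hold these groups and no others, predicts lower correlation between probes of a gene there. The test gave -0.0821 (-0.410 to 0.142) and decided nothing. The median absolute log2 difference between 2 probes of a gene was larger in HepG2 (0.73) and NHEK (0.57). It was 0.23 in HMEC, 0.21 in HASMC and 0.21 in NHA. The SD of the group mean over probes was also larger in HepG2 (1.84) and NHEK (1.42) than in HMEC (1.29), HASMC (0.95) and NHA (1.19). Whether a batch underlies this was not tested, so such a batch and the cell types cannot be told apart. A likeness of the cell types themselves may also account for the NHEK correlations and was not tested.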

How the results depend on the processing

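Values for single spots, dye orientation, 1 orientation, turned signs, zeros and limits as missing, and subsets of serial numbers other than those of HUVEC were chosen after seeing the data, and the cause of a change was not tested unless stated. Of counts under median centring, that of HMVEC against large-vessel cells moved by over 1.5 times, to 73. Quantile normalization gave 197 for HMVEC, 60 for arterial cells against HUVEC, 52 for HCAEC against HAEC and 138 for NHEK against HMEC. Averaging consecutive serial numbers gave 6 for arterial cells. Fits on the compared groups alone gave 208 for HMVEC, 9 for arterial cells and 0 for HCAEC against HAEC by limma (106 at an unadjusted p under 0.05), and HUVEC replicates 9 and 10 alone gave 0 for arterial cells by limma (23 at an unadjusted p under 0.05). That fit was not run for endothelial against non-endothelial cells, which use all groups, nor for restricted probes.

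Single spots, 1248 tests in place of 672, gave 684 for endothelial against non-endothelial cells, 367 for HMEC, 269 for HASMC, 355 for NHA, 741 for HepG2, 628 for NHEK, 188 for HMVEC, 38 for arterial cells, 27 for HCAEC against HAEC and 506 for NHEK against HMEC, since more tests were counted. Arrays of 1 orientation gave 67 for HMVEC and 22 for HCAEC against HAEC. Without HAEC and HCAEC replicates 1 and 2 the counts were 221 for HMVEC, 140 for arterial cells, 43 for HCAEC against HAEC and 15 restricted probes. With the signs of replicate 2 turned they were 82 and 25 for arterial cells and HCAEC against HAEC, and with dye orientation, kept as read before turning, as a covariate as well 106 and 30. Arrays 1 to 40 alone gave 207 for endothelial against non-endothelial cells, with DDX3X (0.26) and RCC2 (0.053) turned in sign and not called. They gave 51 restricted probes, but hold only HUVEC, HMVEC, HMEC, HASMC and NHA. A probe there had only to pass the contrasts between these groups, so that count cannot be compared with the count over all groups. Arrays 57 to 66 alone gave 275 for arterial cells and 292 for HCAEC against HAEC.

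Leaving out each array in turn gave 361 to 387 for endothelial against non-endothelial cells, 21 to 27 restricted probes, 213 to 237 for HMEC, 154 to 185 for HASMC, 203 to 242 for NHA, 360 to 401 for HepG2, 309 to 351 for NHEK, 80 to 146 for HMVEC, 12 to 56 for arterial cells, 3 to 26 for HCAEC against HAEC and 223 to 281 for NHEK against HMEC. Of 141 values of named genes, 132 kept direction and call under centring, 138 under quantile normalization, 124 with serial numbers averaged, 138 with robust empirical Bayes, 139 with dye orientation as a covariate and 132 on 1 orientation. Fits on the compared groups kept 95 of 117, HUVEC replicates 1 to 8 alone 117 of 121, and HUVEC replicates 9 and 10 alone 0 of 17. All differences kept their sign there, with POSTN at 2.94, CCL2 at 1.62, B2M at 0.96 and FAM110D at -2.31, but METTL14 only at -0.51, HNRNPF at -0.39, PRKDC at -0.34, TFG at -0.31 and PSMD2 at -0.24. Turning replicate 2 of HAEC and HCAEC kept 130 of 131, turning replicate 1 kept 121 of 131, leaving out HepG2 and NHEK kept 21 of 24, and arrays 1 to 40 kept 51 of 60, with 2 reversed. Signal over background is not in the deposited ratios.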

Other observations

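The haemostasis genes and the correlations of group means were picked out for this part after the results were seen. The splits that keep consecutive arrays together were also chosen then, while the other splits were planned.

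Genes of haemostasis were compared between each non-endothelial type and endothelial cells. PROCR, the receptor of protein C, was lower in HMEC (-1.74 ± 0.33), HASMC (-1.66 ± 0.33), NHA (-2.40 ± 0.33), HepG2 (-4.18 ± 0.37) and NHEK (-1.65 ± 0.37). THBD was lower in NHA (-1.97 ± 0.45) and HepG2 (-1.35 ± 0.50), and stood at -0.10 in HMEC, 0.50 in HASMC and 0.71 in NHEK without passing the test. Of the 6 genes measured, HepG2 had 6 lower, NHA 4 lower and 2 higher, NHEK 3 lower, HMEC 2 lower and 1 higher, and HASMC 2 lower and 2 higher, with the same counts adjusted over the list alone, and the list passed camera in none of these 5 comparisons. Several of these genes had probes called in opposite directions, namely VWF (-3.34 and 1.11), ANXA5 (-0.66 and 3.52) and TFPI (-0.49 and 1.18) in HepG2, ANXA5 (-1.18 and 2.79) and THBS1 (1.15 and -1.45) in NHEK, and TFPI in HMEC (0.81 and -4.28), HASMC (0.85 and -0.96) and NHA (0.73 and -2.69). Of the differences between the types, only NHEK against HMEC was tested. There TFPI (-0.84, adjusted p = 0.0011 by limma) and ANXA5 (-1.23, adjusted p = 3.6e-06) were lower in NHEK. The other ANXA5 probe was called in the opposite direction (2.77). VWF, THBD, PROCR and THBS1 did not pass.

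HASMC and NHA had the highest correlation of group means across probes among the 36 pairs of groups (0.823), followed by HepG2 and NHEK (0.819). HUVEC correlated at 0.544 with HAEC, 0.429 with HCAEC and 0.0767 with HMVEC, and HAEC at 0.524 with HCAEC. HUVEC arrays hold HUVEC in both channels, so their mean is not an expression profile of HUVEC against another cell type. All HAEC and HCAEC arrays had a positive orientation, which was read from correlation with that mean, while HMVEC had 4 of each sign. The correlations with HUVEC therefore do not rank likeness to HUVEC. Probes are not independent replicates, and all groups share a reference.

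Splits of the same arrays into groups of the same sizes were drawn, 100 for each result with the real split included. For endothelial against non-endothelial cells 1 split, the real one, called as many probes (376, the highest other 50), and a chance division of single arrays can be excluded. The same held, with 1 split as large, for HMEC (225, the highest other 135), HASMC (178 and 15), NHA (226 and 108), HepG2 (398 and 102), NHEK (341 and 252), HMVEC (114 and 1), NHEK against HMEC (255 and 219) and the restricted probes (25 and 0). For arterial cells against HUVEC 1 split was as large (23, the highest other 17), but these splits treat arrays as independent. Splits that keep arrays of consecutive serial numbers together gave at least 23 probes in 6 of 100, with up to 181, so chance cannot be excluded there. For the other results named so far 1 such split, the real one, was as large, with the highest other at 237 for endothelial against non-endothelial cells, 159 for HMEC, 115 for HASMC, 138 for NHA, 278 for HepG2, 235 for NHEK, 83 for HMVEC, 191 for NHEK against HMEC (35 splits) and 0 for the restricted probes. For HCAEC against HAEC 5 of the 100 splits called at least the real 14 probes, so chance cannot be excluded. The highest other split there called 47, several times the real count, while the median of the other splits was 0. What sets that split apart was not tested. Keeping consecutive arrays together leaves 10 splits there, too few for a share under 0.05. Of these, 4 called at least the real 14 probes, the real split included (the highest other 46).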
